A study of Homo sapiens with 5 samples.

How the data were processed

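Ribosome footprints of 5 HAP1 libraries, 2 wild type and 3 METTL18 knockout, were measured. Per the labels' protocols, cells were lysed with cycloheximide, the lysate was digested with RNase I, monosomes were taken from a sucrose gradient, footprints of 28 to 32 bases were selected on a gel, and the adapters carried 4 randomized bases to lessen ligation bias. Whether those bases were used to remove duplicate reads is not given in the sources used here, so counting intervals and floors cover counting error only. The labels name the molecule as polyA RNA, which differs from the footprints the protocol describes. Per the submitters' processing notes, Bowtie and the human build hg38 were used, with no version named; the annotation release, the counting tool and its treatment of reads that match several places are not given in the sources used here. No matched RNA-seq was used here, so translational efficiency was not computed.

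The authors deposited raw counts in 1 table of 14084 rows, each an Ensembl transcript paired with a gene symbol. The values were whole numbers with a different total in each library, and 387 rows held no count in any library. For the 39 symbols with more than 1 row, the row with the most counts stood for the gene in lists and named genes. GENCODE release 29, on the same build, gave coordinates, coding length and GC content for 13956 transcripts (99.1%). The list of mitochondrially encoded proteins was not analysed here, since none of its members was measured.

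Groups came from the genotype in the labels. Counts were tested with edgeR 4.0.16 in R 4.3.3 (robust quasi-likelihood fit, TMM factors of 1.12 and 1.12 in the wild type and 0.927, 0.924 and 0.932 in the knockout, filterByExpr with a minimum count of 10 and a minimum total of 15), with the group as the sole term and an adjusted p under 0.05 as the threshold. Gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01) where at least 5 members were measured, and again with an estimated correlation and with fry, which asks whether a list's genes move one way and does not compare it with other genes. With an estimated correlation, camera uses the few residual degrees of freedom of 5 libraries, so its p-values can be larger even where the correlation is small. The median of each list was also set beside those of 10000 random lists of the same size, matched on mean log2 CPM or on coding length, which was chosen after seeing the data. The 33 gene lists, the design, the alternatives other than those added after seeing the data, and the rule for named genes were fixed before the data were examined. That rule named METTL18, RPL3 and the other methyltransferases of the list, the 12 largest rises and 12 largest falls among genes past the threshold with a mean log2 CPM of at least 3 and no overlap between groups, and up to 4 members of each list with the smallest adjusted p. Some of the genes it named are not reported here.

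Where every library of a group had 0 counts, the fold was computed against a floor of 3 counts over that group, which is 0.263 CPM in the wild type and 0.0636 CPM in the knockout; with 1 to 3 counts the ratio has an exact 95% interval from the binomial distribution. Medians of the 33 lists were the same, where they had one, with members at 0 set to their bound. The depth of 4887380 to 17629199 counts sets the precision: on counts simulated from the wild-type means and the real library sizes, with 50 genes changed at each size, the test recovered 34% of genes changed 1.25-fold, 74% at 1.5-fold, 92% at 2-fold and 98% at 4-fold, with 11012 genes tested, and 4.84% of its calls fell on unchanged genes. In that simulation 11095 genes were unchanged, whereas 74.4% of tested genes were called in the data, so these shares may not carry over.

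The 2 wild-type libraries were compared over 10241 genes with at least 20 counts in the pair: their chi-square per degree of freedom was 1.14 (p = 8.02e-22), which takes reads as independent molecules. Duplicate reads alone might raise this value, so it does not by itself show separate libraries, and they were counted as 2 because the labels list them as separate samples. The same value was 2.73 to 3.48 between knockout libraries and 102 to 110 between groups. It grows with depth where libraries differ beyond counting error, and the knockout libraries were 3.33-fold deeper. The pairs are therefore not compared at a common depth. The first principal component of log2 CPM held 94.3% of the variance and separated the groups. Alternatives were other scaling factors (RLE, upper quartile), DESeq2 1.42.0, limma-voom, no low-count filter or a mean CPM of at least 10, a required fold of 1.5 (glmTreat), a non-robust fit, the replicate number as a block, and each library left out in turn. Thinning the knockout libraries to the mean wild-type total, summing the wild-type libraries and scaling by total counts were added after seeing the data. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9 were used for annotation and figures.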

Results

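Ribosome footprints were counted in HAP1 cells, an established near-haploid human line in which disrupting a single copy can inactivate a gene. The 5 libraries form 2 groups, wild type (n = 2) and METTL18 knockout (n = 3). METTL18 is a methyltransferase that modifies a histidine of RPL3, a protein of the large ribosomal subunit, and the study's title ties this to ribosome formation and function. Footprints are RNA fragments that a ribosome shields from nuclease. A gene's count rises with the amount of its mRNA and with the ribosomes on each copy, and these parts were not separated here. The wild-type libraries held 5302160 and 4887380 counts, and the knockout libraries 16339574, 17629199 and 16921863, a 3.33-fold difference in mean depth that runs with the groups. Levels are CPM after TMM scaling, given as mean ± SD over the libraries of a group. Adjusted p-values come from the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment unless another test is named, and fold changes are knockout over wild type. The labels do not say that the libraries come from separate cultures or clones, so these p-values measure only the spread between these libraries, which may be technical.

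METTL18 itself was lower in the knockout libraries. Its row (transcript ENST00000310392, hg38 chromosome 1, 169792529 to 169794966, minus strand) held 33 and 32 counts in the wild-type libraries and 33, 32 and 34 in the deeper knockout libraries. That is 5.71 ± 0.211 CPM (SD, n = 2) against 2.10 ± 0.117 CPM (SD, n = 3), a log2 fold change of -1.44 (SE 0.247, adjusted p = 2e-06, edgeR quasi-likelihood test). Footprints remained on the gene at a reduced level in all 3 knockout libraries. The position and kind of the mutation are not given in the sources used here, so these counts do not tell whether any METTL18 protein was made. RPL3 (transcript ENST00000216146, hg38 chromosome 22, 39312884 to 39319771, minus strand), the substrate, rose from 1830 ± 54.9 to 3729 ± 50.6 CPM, a log2 fold change of 1.03 (SE 0.0353, adjusted p = 4.82e-27, edgeR quasi-likelihood test). This rise was not particular to RPL3: the 42 large-subunit ribosomal protein genes, RPL3 included, had a median of 0.947 and reached 1.99.

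**Figure D1:**
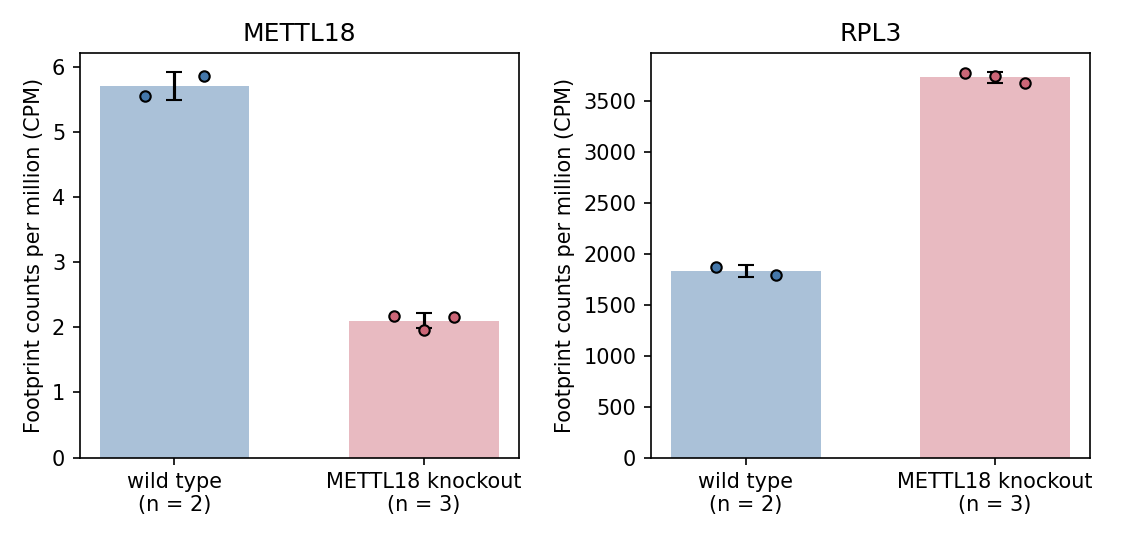
Footprint CPM for METTL18 (left) and RPL3 (right), with 1 point per library, bars at the group mean and error bars of 1 SD. METTL18 lies at 5.71 CPM in the wild type and 2.10 CPM in the knockout, and RPL3 at 1830 and 3729 CPM.

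Other enzymes that methylate histidine, ribosomes or elongation factors moved both ways. Of 13 measured members of this list, METTL18 included, 5 rose, 5 fell and 3 did not pass, also when adjusted over the list alone. METTL13, which methylates elongation factor EEF1A, rose (log2 fold change 0.86), as did ZCCHC4 (0.84), SETD3, the actin histidine methyltransferase (0.59), NTMT1 (0.56) and TRMT112, an activator of several methyltransferases (0.45). SMYD5 (-0.78), METTL5 (-0.34), CARNMT1 (-0.25) and NSUN5 (-0.20) fell. METTL9, another histidine methyltransferase, stood at 19.4 ± 2.26 CPM in the wild type and 19.2 ± 0.921 CPM in the knockout (adjusted p = 0.936, edgeR quasi-likelihood test). EEF2KMT (log2 fold change 0.17) and N6AMT1 (-0.38) did not pass. Without wild type replicate 2 the calls of CARNMT1 (-0.14) and NSUN5 (-0.17) were lost, and that of CARNMT1 also without METTL18 knockout replicate 2 (-0.23), without a low-count filter and with DESeq2. With total-count scaling, chosen after seeing the data, METTL9 (-0.28) and N6AMT1 (-0.65) passed as lower. The list did not stand apart from other genes (camera adjusted p = 0.994). Of 6 measured neighbours of METTL18 on chromosome 1, KIFAP3 (-0.54) and NME7 (-0.50) fell and 4 did not pass, also when adjusted over the list alone (camera adjusted p = 0.789). GORAB, among these 4 (0.37, adjusted p = 0.0946, edgeR quasi-likelihood test), passed as higher without METTL18 knockout replicate 3 (0.43, adjusted p = 0.0481).

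The 2 groups differed at most genes. Of 11335 genes tested, 4288 rose and 4143 fell in the knockout, 74.4% in all, and 2904 did not pass. With a fold of at least 4, 502 rose and 591 fell. Among the largest rises, ZFP42, a pluripotency marker, DNMT3L, a cofactor of germline DNA methylation, and MEIOB, a meiotic recombination protein, had 0 counts in both wild-type libraries. Against a floor of 3 counts over the wild-type group, ZFP42 (142 ± 3.42 CPM in the knockout) was at least 540.9-fold higher, MEIOB at least 338.6-fold and DNMT3L at least 319.3-fold. OLFML3 was at least 285.2-fold higher, the zinc finger gene ZNF556 at least 219.2-fold, PCDHGB5 at least 147.3-fold and B4GALNT2 at least 138.3-fold. ZNF729 was at least 127.7-fold higher, the histone demethylase KDM4E at least 111.9-fold, ZIK1 at least 108.5-fold and DTNA at least 91.45-fold. AMBN, the enamel matrix protein ameloblastin, had 1 count in the wild type, in replicate 2, and 12506 in the knockout, a ratio of 3023 (95% counting interval 542 to 119400).

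Among the largest falls, CHL1, a neural cell adhesion protein, had 488 counts in the wild type and 2 in the knockout, both in replicate 3, a ratio of 1009 (95% counting interval 278 to 8359). MGMT, the enzyme that repairs alkylated guanine, fell from 42.3 ± 4.21 to 0.194 ± 0.177 CPM, a log2 fold change of -7.72. SERPINF1, a secreted serpin, fell from 314 ± 0.958 to 1.63 ± 0.373 CPM (-7.58), ITM2A from 374 ± 13.02 to 5.65 ± 0.552 CPM (-6.04), and the drug efflux pump ABCB1 from 103 ± 0.262 to 1.252 ± 0.0780 CPM (-6.36). The protease HTRA1 (-7.70), AFF2 (-7.55), the DNA sensor IFI16 (-6.16), ARHGEF6 (-5.43), FAM129A (-5.28), the tight-junction protein CLDN1 (-5.12) and POF1B (-4.98) fell as well. Without METTL18 knockout replicate 1, the log2 fold changes of IFI16 (-7.37) and MGMT (-8.66) were larger. Knockout values did not overlap wild-type values for 9467 genes, 83.5% of those tested, where chance gives 20%. Total-count scaling in place of TMM moved the median of all genes from 0.0161 to -0.26 and the calls to 2982 up and 5597 down. List medians and gene values given with that scaling carry this shift. When a fold above 1.5 was required, 4140 genes passed, 2011 up and 2129 down, and the calls of 16 genes followed as targets or list examples were lost, among them SETD3, METTL5, TRMT112, NTMT1, CARNMT1, NSUN5, KIFAP3 and NME7.

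**Figure D2:**
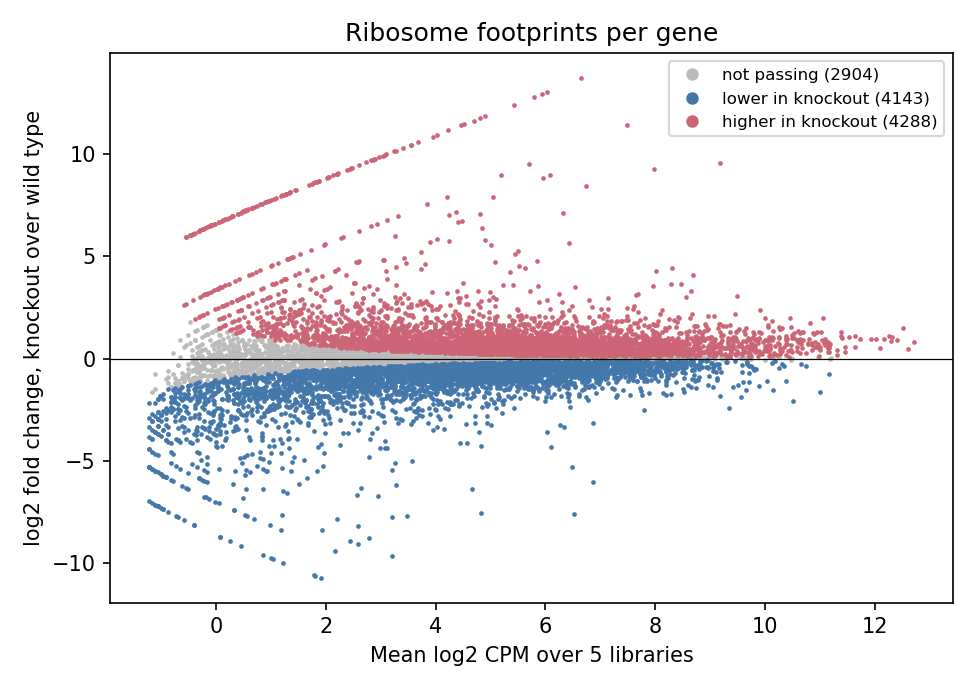
Log2 fold change, knockout over wild type, against mean log2 CPM over the 5 libraries, with 1 point per gene for the 4288 genes that rose (red), the 4143 that fell (blue) and the 2904 that did not pass (grey). The diagonal lines of points are genes with 0 or very few counts in 1 group, whose fitted fold changes depend on the prior count and are not bounds.

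Ribosomal protein genes rose. Of 42 large-subunit genes, 40 rose, none fell and 2 did not pass. The median log2 fold change was 0.95 (camera adjusted p = 2.99e-10; adjusted p = 0.142 with an estimated correlation), and the counts were the same when adjusted over the list alone. RPL7A rose from 755 ± 20.9 to 3002 ± 29.7 CPM (log2 fold change 1.99), RPLP1, a protein of the ribosomal stalk, from 435 ± 15.3 to 1537 ± 57.3 CPM (1.82), RPL23A by 1.74 and RPL29 by 1.56. Of 26 small-subunit genes, 25 rose and 1 fell. Adjusted over the list alone the counts were the same, and the median log2 fold change was 0.75 (camera adjusted p = 1.1e-06; adjusted p = 0.142 with an estimated correlation). RPS29 (1.51), RPS23 (1.31) and RPS3A (0.98) rose. RPS27L, named after its value was seen, was the gene that fell (-0.97). Together the 2 lists took 8.30% ± 0.0503 of the counts in the wild type (SD, n = 2) and 12.0% ± 0.0403 in the knockout (SD, n = 3), a difference of 3.73 percentage points. Many of these genes have processed pseudogenes, and how reads shared with them were counted is not given in the sources used here.

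Factors that build ribosomes mostly rose. Among 60 factors of the large subunit, 38 rose, 14 fell and 8 did not pass. Their median log2 fold change was 0.32 (camera adjusted p = 0.0114; adjusted p = 0.289 with an estimated correlation), with the same counts when adjusted over the list alone. PA2G4 (0.94) and ZNF622 (1.49), both factors of late pre-60S particles, rose, and DKC1, the pseudouridine synthase of H/ACA particles, fell (-0.82). Among 53 factors of the small subunit and its processome, 34 rose, 11 fell and 8 did not pass. The median log2 fold change was 0.30 (camera adjusted p = 0.0124; adjusted p = 0.266 with an estimated correlation), and the counts were the same when adjusted over the list alone. Nucleolin (NCL) rose from 2190 ± 3.55 to 4222 ± 158 CPM, and BYSL, a factor of late small-subunit assembly, by 1.61. Of 18 genes of RNA polymerase I and rDNA transcription, 15 rose, none fell and 3 did not pass, with POLR2L up by 1.31 and POLR1C by 0.97. Adjusted over the list alone the counts were the same, and the median log2 fold change was 0.55 (camera adjusted p = 0.00102; adjusted p = 0.150 with an estimated correlation). With total-count scaling neither list of assembly factors passed, with medians of 0.0488 for the large subunit (camera adjusted p = 0.0879) and 0.0300 for the small one (camera adjusted p = 0.0566). As fitted, both medians lay inside the central 95% of medians of random lists matched on abundance, which ended at 0.36 for each, and above that of lists matched on coding length, which ended at 0.26 for each.

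Genes that charge tRNA fell. Of 21 cytosolic aminoacyl-tRNA synthetases and their scaffold proteins, 15 fell, 3 rose and 3 did not pass. Their median log2 fold change was -0.64 (camera adjusted p = 0.00193; adjusted p = 0.150 with an estimated correlation), with the same counts when adjusted over the list alone. IARS, the isoleucine enzyme, fell from 2750 ± 34.3 to 652 ± 9.91 CPM (-2.08), and those for methionine (MARS, -1.84), glutamate and proline (EPRS, -1.55) and leucine (LARS, -1.52) fell too. Of 41 initiation factors, 22 rose, 10 fell and 9 did not pass (camera adjusted p = 0.0891). Without a low-count filter this list passed as higher, with a median of 0.20 (camera adjusted p = 0.0475). EIF4EBP1, a repressor of cap-dependent initiation, fell by 1.70 on the log2 scale, EIF4A2 rose by 1.94 and EIF4B by 1.42. Of 31 elongation, release and quality control factors, 18 rose, 6 fell and 7 did not pass (camera adjusted p = 0.0955). For these last 2 lists the counts were the same when adjusted over the list alone, and total-count scaling turned the medians from 0.18 to -0.0922 for initiation and from 0.26 to -0.0105 for elongation. Those turns follow from the shift of all genes with that scaling.

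Targets of 2 stress pathways fell. Of 30 genes of the integrated stress response and its transcription factor ATF4, 22 fell, 7 rose and 1 did not pass. The median log2 fold change was -1.13 (camera adjusted p = 0.000611; adjusted p = 0.250 with an estimated correlation), and the counts were the same when adjusted over the list alone. The pseudokinase TRIB3 fell from 229 ± 2.68 to 22.4 ± 2.03 CPM (-3.36), asparagine synthetase (ASNS) from 1392 ± 3.51 to 381 ± 20.1 CPM (-1.87), and the secreted factor GDF15 (-3.61) and PCK2 (-2.04) fell too. Of 23 p53 targets, 19 fell, 1 rose and 3 did not pass. Adjusted over the list alone the counts were the same, and the median log2 fold change was -0.99 (camera adjusted p = 6.37e-06; adjusted p = 0.142 with an estimated correlation). The cell-cycle inhibitor CDKN1A fell from 221 ± 4.26 to 11.2 ± 0.405 CPM (-4.30), MDM2, the ubiquitin ligase of p53, from 1330 ± 14.5 to 250.1 ± 5.69 CPM (-2.41), and SESN1 (-2.33) and TNFRSF10B (-1.78) fell too.

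Histone and replication genes rose. Of 45 replication-dependent histone genes, 43 rose, 1 fell and 1 did not pass. Their median log2 fold change was 1.53 (camera adjusted p = 1.2e-11; adjusted p = 0.150 with an estimated correlation), with the same counts when adjusted over the list alone. HIST1H3C rose from 1.22 ± 0.176 to 918 ± 19.3 CPM, HIST1H3J from 0.611 ± 0.0882 to 381 ± 7.36 CPM, HIST4H4 from 21.9 ± 3.80 to 474 ± 9.16 CPM and HIST1H2BB from 68.9 ± 1.67 to 545 ± 18.9 CPM. Histone genes share stretches of sequence, and how shared reads were counted is not given in the sources used here, so the values of single copies are uncertain. In HIST1H3C and HIST1H3J, shares of 0.90 and 0.995 of the windows of 28 bases occurred in no other coding sequence of the table. Counts were also summed over the tested genes of each family, chosen by symbol, some of them outside the list. The log2 ratios of knockout to wild type were 0.80 for H2B (12 genes), 1.02 for H2A (13) and 1.08 for H3 (11). They were 1.24 for H4 (10) and 1.28 for H1 (4). All lay below the median of the single genes of the list, which is not the same set. Of 44 genes of the G1/S transition and DNA replication, 32 rose, 7 fell and 5 did not pass. When adjusted over the list alone, 33 rose and 7 fell, and the median log2 fold change was 0.56 (camera adjusted p = 0.000524; adjusted p = 0.142 with an estimated correlation). The licensing factor CDT1 rose by 2.42, GINS2 by 1.83, and the helicase subunits MCM4 by 1.18 and MCM6 by 1.08. Of 41 genes of G2 and mitosis, 25 rose, 11 fell and 5 did not pass, also when adjusted over the list alone (camera adjusted p = 0.0900). ANLN, a cytokinesis scaffold, rose by 1.90, and topoisomerase TOP2A fell by 1.11 on the log2 scale.

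Sterol synthesis genes rose. Of 26 genes, 23 rose, 2 fell and 1 did not pass. Adjusted over the list alone the counts were the same, and the median log2 fold change was 1.08 (camera adjusted p = 2.8e-06; adjusted p = 0.142 with an estimated correlation). HMGCS1 rose from 127 ± 2.09 to 562 ± 24.3 CPM (2.15) and MSMO1 by 2.43. Of 31 cytosolic chaperones, 26 rose, 1 fell and 4 did not pass. Their median log2 fold change was 0.595 (camera adjusted p = 1.45e-05; adjusted p = 0.150 with an estimated correlation), with the same counts when adjusted over the list alone. HSP90AB1 rose from 2759 ± 17.9 to 7824 ± 162 CPM and HSPA8 from 3087 ± 11.1 to 6355 ± 125 CPM.

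Nuclear genes of mitochondria and of glycolysis rose more often than they fell. Of 68 subunits of oxidative phosphorylation, 44 rose, 16 fell and 8 did not pass, with COX6B1 up by 1.69. The median log2 fold change was 0.41 (camera adjusted p = 0.00261; adjusted p = 0.239 with an estimated correlation), and the counts were the same when adjusted over the list alone. Of 72 mitochondrial ribosomal proteins, 40 rose, 16 fell and 16 did not pass, with MRPL17 up by 1.23 and MRPL24 lower (-1.18). When adjusted over the list alone, 42 rose and 16 fell, and the median log2 fold change was 0.22 (camera adjusted p = 0.0192; adjusted p = 0.192 with an estimated correlation). Total-count scaling turned their median to -0.0555 and the call was lost (camera adjusted p = 0.158), as it was with a mean CPM of at least 10 (camera adjusted p = 0.0644). Of 27 genes of glycolysis and hypoxia, 16 rose, 6 fell and 5 did not pass, with GAPDH up by 0.95 and HK2 by 1.54. When adjusted over the list alone, 17 rose and 6 fell, and the median log2 fold change was 0.46 (camera adjusted p = 0.0294; adjusted p = 0.192 with an estimated correlation). That call was lost without wild type replicate 2, where the median was 0.458. It was also lost with the knockout libraries thinned to the wild-type depth, chosen after seeing the data (median 0.43, camera adjusted p = 0.0502). The medians of these 3 lists lay inside the central 95% of medians of random lists matched on abundance, which ended at 0.42 for oxidative phosphorylation, 0.295 for mitochondrial ribosomal proteins and 0.55 for glycolysis. With lists matched on coding length, those of oxidative phosphorylation (upper end 0.44) and mitochondrial ribosomal proteins (0.39) also lay inside, and that of glycolysis lay above (0.42).

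Zinc finger genes of the ZNF series, many of them DNA-binding repressors, rose. Of 388 genes, 254 rose, 37 fell and 97 did not pass. The median log2 fold change was 0.76 (camera adjusted p = 3.97e-09; adjusted p = 0.142 with an estimated correlation), and the counts were the same when adjusted over the list alone. With the 16 genes at 0 counts in a group set to their bound the median was 0.76. ZNF486 rose from 0.864 ± 0.445 to 41.8 ± 2.78 CPM, and its log2 fold change was 6.22 without wild type replicate 1, against 5.56 with all libraries. ZNF257 had 2 counts in the wild type and 2050 in the knockout, a ratio of 248 (95% counting interval 68.5 to 2047). The 189 ZNF genes on chromosome 19, where many lie in clusters, had a median of 1.20, the 199 elsewhere 0.43, and the 638 other genes tested on chromosome 19 0.18; this split was made after the values were seen and the difference was not tested.

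**Figure D3:**
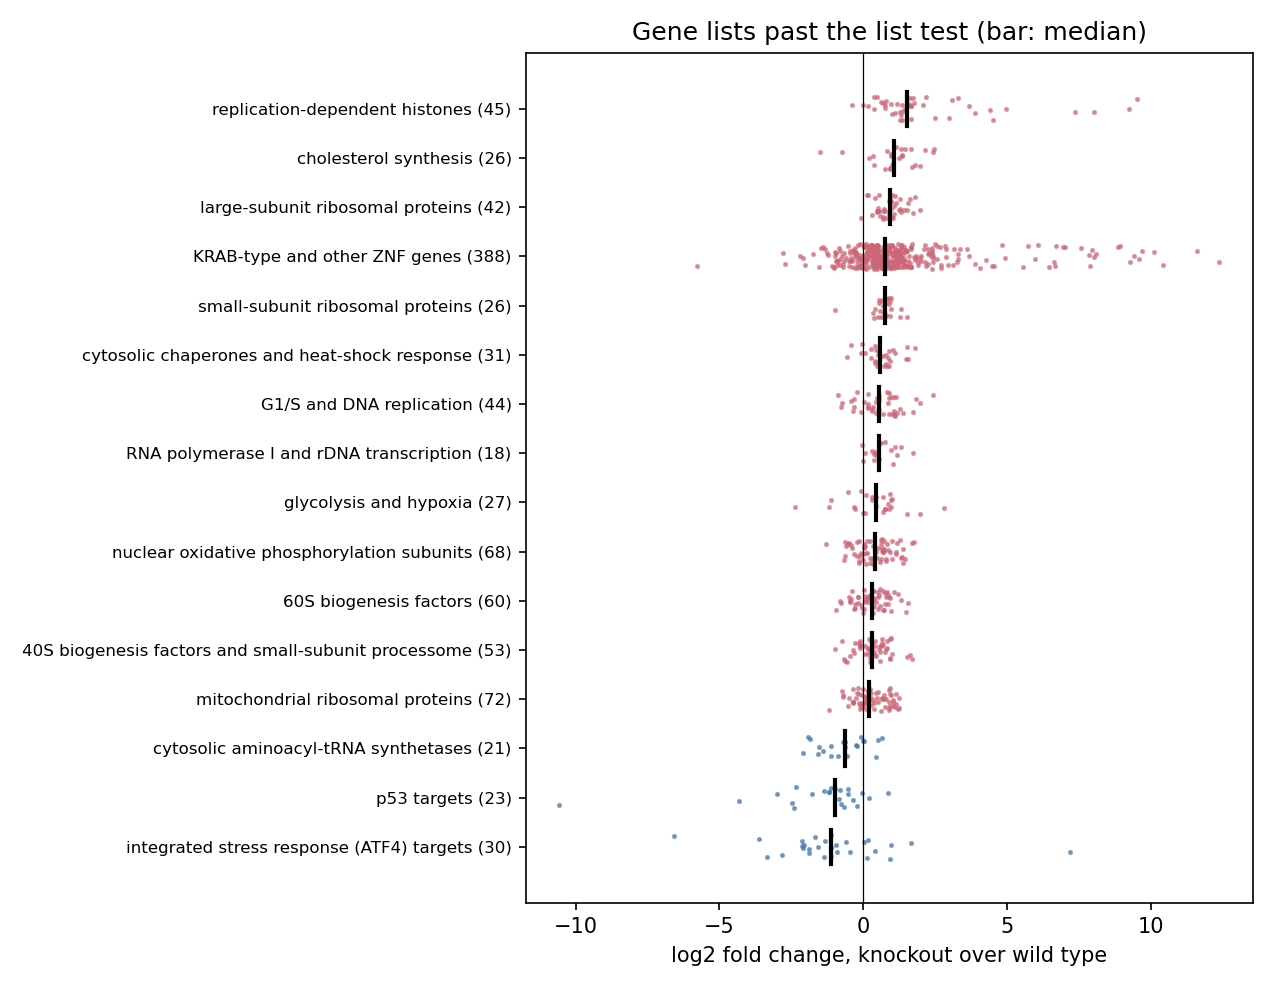
Log2 fold change, knockout over wild type, of each measured member of the 16 gene lists that passed the camera test, with 1 point per gene and a bar at the list median. Medians run from -1.13 for the integrated stress response to 1.53 for replication-dependent histones, with TMM scaling; fitted values of genes near 0 counts in 1 group are not bounds.

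Markers of other cell types moved in both directions. Among 8 mesenchymal markers, 6 rose, none fell and 2 did not pass, and vimentin (VIM) rose from 129 ± 12.3 to 1069 ± 24.4 CPM. Among 10 epithelial and endodermal markers, 6 rose, 2 fell and 2 did not pass. The splicing regulator ESRP1 fell from 51.2 ± 1.22 to 9.16 ± 0.741 CPM. CDH1 went the other way, with 1 count in the wild type and 582 in the knockout, a ratio of 140.7 (counting interval 25.15 to 5566). CLDN7 was also higher, with log2 fold changes of 4.199 to 5.294 with 1 library left out. Among 9 neural markers, 4 rose, 4 fell and 1 did not pass, with the neuronal tubulin TUBB3 up by 3.55 and MAP2 lower (-3.91). Among 5 haematopoietic markers, 2 rose, 2 fell and 1 did not pass, with GATA2 up by 1.87 and CORO1A by 1.36, and TAL1 (-2.13) and KIT (-0.50) lower. The call of KIT was lost without wild type replicate 2 (-0.40, adjusted p = 0.104, edgeR quasi-likelihood test). The counts of these 4 lists were the same when adjusted over the list alone. None of them passed the camera test, with an adjusted p of 0.0775 for mesenchymal, 0.20 for epithelial, 0.977 for neural and 0.977 for haematopoietic markers. Without a low-count filter the mesenchymal list passed as higher, with a median of 0.72 against 0.45 (camera adjusted p = 0.0425).

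Genes of protein folding in the endoplasmic reticulum, protein breakdown, lipids, oxidants and growth did not pass the camera test as lists. Of 28 genes of the endoplasmic reticulum stress response, 8 rose, 14 fell and 6 did not pass (camera adjusted p = 0.255), and SEL1L, a subunit of the degradation complex of that compartment, fell by 1.88 on the log2 scale. Of 30 proteasome subunits, 14 rose, 12 fell and 4 did not pass (camera adjusted p = 0.847), with PSMB5 up by 0.65 and PSMC4 lower (-0.83). Of 11 genes of fatty acid synthesis, 9 rose and 2 fell (camera adjusted p = 0.101), with the desaturase SCD up by 1.30. Of 24 antioxidant genes, 14 rose, 5 fell and 5 did not pass (camera adjusted p = 0.127), and the peroxiredoxin PRDX1 rose from 503 ± 14.8 to 1952 ± 46.5 CPM. Of 24 genes of MYC and growth control, 10 rose, 8 fell and 6 did not pass (camera adjusted p = 0.847), and MYC itself rose from 272 ± 5.40 to 546 ± 22.3 CPM. The counts of these 5 lists were the same when adjusted over the list alone. Of 21 interferon-stimulated genes, 3 rose, 13 fell and 5 did not pass (camera adjusted p = 0.0955), with IFITM3 up by 3.01 and the RNA sensor IFIH1 lower (-2.95). When adjusted over the list alone, 4 rose and 13 fell. Of 41 extracellular matrix and adhesion genes, 21 rose, 17 fell and 3 did not pass (camera adjusted p = 0.811), with the collagen COL4A6 up by 3.29 and the integrin ITGA4 lower (-2.42). When adjusted over the list alone, 21 rose and 18 fell, and the median of 0.16 turned to -0.11 with total-count scaling. In all, 16 of 32 lists passed the camera test with its preset correlation, 13 up and 3 down, and 0 passed with an estimated correlation. For sterol synthesis the estimated correlation (0.00116) was below the preset 0.01, yet its unadjusted camera p rose from 4.37e-07 to 0.0114. For the G1/S genes it was -0.0139, and the unadjusted camera p rose from 0.000131 to 0.0196. Loss of those calls therefore does not show correlation between members. The medians of 11 of the 16 lists that passed lay outside the central 95% of random lists matched on abundance and 14 outside that of lists matched on coding length. Of these, cytosolic chaperones on abundance (0.595, upper end 0.594) and RNA polymerase I on coding length (0.553, upper end 0.546) lay at the edge. Small-subunit ribosomal proteins on abundance (0.746, upper end 0.725) lay near it. Among the 16 that did not pass, the endoplasmic reticulum list (median -0.16) lay below the central 95% on abundance, which began at -0.0723. On coding length, G2 and mitosis (0.28) and the matrix genes (0.16) lay above it, with upper ends of 0.23 and 0.15, and the interferon genes (-0.56, with 20 members that have a coding length) below it, with a lower end of -0.45.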

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

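Thinning, summing the wild-type libraries and total-count scaling were chosen after seeing the data, the other alternatives before. The count of changed genes, 8431 as reported, lay between 6111 and 8760 under every alternative run except the required fold of 1.5, where a stricter null gave 4140. It was 7391 to 8284 with 1 library left out, where a lone wild-type library is assumed to vary like the knockout, 7597 with DESeq2 and 7691 after thinning, of which 7537 were called in the same direction before it. METTL18 stayed lower wherever it was tested, from -1.71 to -1.40, and the filter at a mean CPM of 10 removed it. RPL3 stayed higher, from 0.75 to 1.06. The labels do not say that replicate numbers pair the libraries, and deviations of same-numbered libraries had r = 0.00853 and 0.0231. With the replicate number as a block, 8476 genes passed over all 5 libraries and 8355 over 2 pairs, and the glycolysis list no longer passed (camera adjusted p = 0.0535 and 0.0515), while GORAB passed as higher (0.45, adjusted p = 0.0409, and 0.44, adjusted p = 0.0436).

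Of the gene list tests, 13 to 18 passed under other scalings, filters, blocks or left-out libraries, 0 with an estimated correlation and 29 with fry, which tests another question. Without the 10 most abundant genes the ribosomal protein share differed by 4.05 percentage points. The direction of a list test or a named gene turned only where it did not pass as reported. Values are median log2 fold changes, whose sign can differ from the direction of the list test. Ranges with 1 library left out cover every such run, whether or not the direction turned in it. For the methyltransferase list they were -0.0537 with upper-quartile factors, -0.0695 after thinning, -0.0112 with fry and -0.13 to 0.0164 with 1 library left out. For proteasome subunits they were 0.0275 at a mean CPM of 10 and -0.18 with total-count scaling, and for MYC and growth control -0.10 at a mean CPM of 10. For haematopoietic markers they were -0.28 without a filter, -0.10 and -0.11 with the replicate block, and -0.17 to -0.0526 with 1 library left out. Among the left-out runs, that list turned only without wild type replicate 1 (-0.17). For neural markers they were 0.65 without a filter, -0.0578 after thinning, -0.31 with total-count scaling, -0.0396 with fry, and -0.0783 to 0.98 with 1 library left out. METTL9 was at 0.0132 without a filter and -0.13 to 0.10 with 1 library left out. Among the left-out runs, METTL9 turned without wild type replicate 2 (0.10) and without METTL18 knockout replicate 1 (0.0086). With total-count scaling EEF2KMT was at -0.0994 and BLZF1 at -0.10. The turns of EEF2KMT and BLZF1 follow from the shift of all genes with that scaling, and the cause of the turns in direction of the list tests and of METTL9 was not tested.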

Other observations

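The tests of a mixed source, of exchanged labels, of depth over all calls and of shared reads over all calls were chosen only after the result was seen. A list of germline and pluripotency genes was written after the largest changes were seen, so members already seen are left out of its test. Of the 80 other members, 24 were tested, and of these 22 rose and 2 fell. Another 21 were in the table with too few counts to test, at mean levels of at most 0.383 CPM in the knockout and 0.542 CPM in the wild type, and 35 were not in the table. The pluripotency factor KLF4 rose from 32.7 ± 1.80 to 293 ± 13.1 CPM, the RNA-binding ubiquitin ligase TRIM71 from 3.52 ± 0.455 to 29.3 ± 1.00 CPM and TDGF1 from 0.703 ± 0.0412 to 17.5 ± 0.688 CPM, while the meiotic gene TEX15 fell from 36.1 ± 0.751 to 15.0 ± 0.388 CPM. These 4 were picked after their values were seen. SOX2, among the members already seen, stood at 553 ± 24.8 and 538 ± 22.0 CPM (adjusted p = 0.406, edgeR quasi-likelihood test). The hypothesis that germline and pluripotency genes lost silencing as a class predicted a median above the central 95% of medians of random lists matched on abundance, which ended at 0.31. The median was 3.35 as fitted and 2.01 with 8 members at their bound. Members silent in both groups drop out of this median, and 56 of the 80 were not tested, so it describes the tested members and does not decide for the class. What brought these rises was not tested.

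A second hypothesis, that footprints on genes rich in tyrosine codons would fall most, was not borne out. The Spearman rho of the tyrosine share with the log2 fold change was -0.0714 across 8123 genes, which are not independent replicates. Tyrosine ranked 6 of the 20 amino acids from the most negative rho, and isoleucine had the most negative (-0.136). Gene totals hold no codon positions, so this says nothing of pauses at single codons.

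Most genes differed between the groups, and depth differed with them. After thinning, 89.4% of all calls remained in the same direction, which argues against depth as the source of most calls; of the 1093 calls with a fold of at least 4, 75.75% remained and the other 265 no longer passed the low-count filter, so depth cannot be told apart for those. Chromosome explained a share of 0.0215 of the variance of fold changes, a GC and length trend 2.02% of it, 92.8% of genes with a fold of at least 4 kept that fold after the trend was removed, and METTL18 moved the way the labels say (-1.44). At or under 0.5 CPM in one group and at or above 10 CPM in the other were 36 genes on in the knockout and 22 on in the wild type, and their median share of windows of 28 bases found in no other coding sequence of the table was 1, while 96.2% of all called genes had such a share of at least 0.9. These values argue against whole-chromosome copy number and a GC or length trend as the whole cause. The same holds for a mixture in 1 group and for reads shared with other coding sequences of the table. Exchanged labels would turn the sign of each fold change, so they could not explain how many genes differ. METTL18 goes with the labels, but it is 1 gene where 1671 fell at least 2-fold, so this is weak evidence. Median log2 fold changes were -0.356 on chromosome 8, -0.258 on X and 0.39 on 19, and -0.107 to 0.11 on the others. The value of 19 includes 189 ZNF genes with a median of 1.20. Its 638 other genes had a median of 0.179, a split made after the values were seen. Copy-number differences of single chromosomes are therefore not excluded. Reads shared with pseudogenes were not tested. The knockout and the clone or culture it came from remain open and untested, since they run with the groups. So does any difference in library preparation or sequencing that ran with the groups, as depth did.

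Ribosomal protein genes rose, though with an estimated correlation between members neither subunit's list passed the camera test (adjusted p = 0.142 for each). With 5 libraries that version of the test has few degrees of freedom. The median log2 fold change of ribosomal protein genes was 0.83 where the central 95% of random lists matched on coding length ended at 0.44, and 0.82 where that of lists matched on abundance ended at 0.55. On abundance the small subunit alone lay near the edge (0.746, upper end 0.725), and the large one further above it (0.947, upper end 0.619). These values argue against a trend with length or abundance as the whole cause, by a narrow margin for the small subunit on abundance. Random lists, though, do not carry the correlation between members. With total-count scaling, which moved all genes alike, the medians were 0.68 for the large and 0.47 for the small subunit. A response to the loss of METTL18 may be an explanation that stays open, untested, beside clone, culture and library preparation.

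HIST1H3C and HIST1H3J were near 0 in the wild type. The share of windows of 28 bases found in no other coding sequence was 0.90 in HIST1H3C and 0.995 in HIST1H3J, which argues against exact sharing of reads with other coding sequences of the table. The summed H3 genes had a log2 ratio of 1.08, and of 0.82 without these copies. Reads moved between H3 copies would leave the sum of the H3 genes unchanged, so they do not account for its rise. For the near absence of these copies in the wild type, only exact sharing of reads was tested. Reads placed on other H3 copies for another reason, or a sequence variant in these copies, could have this effect. So could the knockout or the history of the culture, and none of these was tested.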
